A study of Homo sapiens with 12 samples.

How the data were processed

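RNA from 12 samples of LNCaP-Abl cells, described as biological replicates within each group, was measured on Illumina bead arrays carrying 47323 probes. LNCaP-Abl is an established prostate cancer cell line derived from LNCaP by long culture without androgen. Per the sample protocols, the cells grew in medium with charcoal-stripped serum, expression of the transfected construct was induced with doxycycline, and biotin-labelled cRNA was hybridised. Samples were grouped by their titles into control vector (3 arrays), wild-type SPOP (3 arrays), SPOP F102C (2 arrays), SPOP F133V (2 arrays) and SPOP F133L (2 arrays).

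Per the file headers, the authors deposited a table of non-normalized signals, which holds for each array an average bead intensity on a linear scale and a detection p-value per probe. Any background subtraction before deposit is not given in the sources used here, and the lowest intensities were 82.4 to 92.1. The authors also deposited processed values that behave as log2 values, with the same median of 7.53 on each of the 12 arrays and a range from 7.30 to 14.7. Lumi is named per the submitters' processing notes, while its version, its settings and the exact transformation behind the deposited log2 values are not given in the sources used here. These processed values ran in the same direction as the log2 intensities of the same arrays and were used only as an alternative. Over the probes kept by the filter described below, Pearson r was 0.991 to 1.000 after rounding.

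The intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative control distribution inferred from the detection p-values. A probe was kept when its detection p-value was under 0.05 on at least 2 arrays, which left 23133 probes. The platform annotation gave 1 gene symbol for 30113 probes, several for 8 and none for 17202, of which 6614 passed the filter. Of the probes with 1 symbol, 30074 had a gene identifier in the NCBI gene table of assembly GRCh38.p14, used only for names, and 0 symbols had to be updated. The probe with the highest mean signal stood for each gene, and 12227 genes were tested. Levels are on this normalized log2 scale.

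A linear model with 5 group means was fitted to all 12 arrays with limma (lmFit and eBayes), with 7 residual and 4.67 prior degrees of freedom. The mutant groups were averaged with equal weight where the mutants are compared as a set. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05, and differences among the 3 mutants were tested with limma's F test. Whether replicates came from separate lines is not given in the sources used here. P-values measure the spread between these arrays, and the small number of arrays limits the precision.

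Before the data were examined, 28 gene lists holding 522 genes were fixed, together with the comparisons and tests. Of these genes 479 had a named probe and 387 were tested, and 27 lists had at least 3 tested genes. The Hedgehog list had 1 tested gene and was left out. Lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. Camera compares a list with all other genes, and its adjusted p-values cover the 27 lists of a comparison. The rotation test fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, was run beside it.

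Genes were named by a rule also fixed beforehand. In each of the 2 main comparisons (wild-type SPOP against control vector, mutants against wild-type SPOP) these were the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between the sides. Of the 10 largest falls in wild-type SPOP against control vector, 1 is not reported here. In the other comparisons they were the 3 largest each way. A short set of SPOP and androgen-induced genes was always named, of which 3 had no probe with a listed symbol and are not analysed here, as were up to 4 members of lowest p from each list discussed. A gene whose probe was detected on no array of a group has only a bound there. Its change is given as at least the fold between the brighter group's mean and the lowest detected signal (or the probe's own signal where higher) of each dimmer array.

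On simulated data for the 12227 genes, the limma fit recovered 100% of genes changed by 1 log2 unit and 44.8% of those changed by 0.5 for wild-type SPOP against control vector. For the mutants against wild-type SPOP these shares were 98.5% and 70.1%, for SPOP F102C against wild-type SPOP 95.5% and 16.4%, and for the F test among the mutants 97.0% and 14.9%. Of 27 unchanged lists camera called 0 in each of the first 3 simulated comparisons. The simulated genes varied independently and the lists were random, so this does not show how often camera calls lists of co-regulated genes.

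The alternatives were other background corrections and normalizations, the authors' processed values, other probe filters, every probe as a feature, the replicate number as a block, another spread model, array weights, fits of only the arrays compared, and leaving out each array in turn. A covariate for the number of detected probes and a scaling to the probes detected on all arrays were added after the data were seen. A block for the bead chip was not run because chip identities are not given in the sources used here. No coordinates were used.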

Results

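The series measured how wild-type and cancer-associated mutant forms of SPOP change gene expression in a prostate cancer cell line. SPOP is the substrate-binding subunit of a CUL3 ubiquitin ligase, and the F102C, F133V and F133L changes lie in its substrate-binding domain. Expression arrays were available for 5 groups of LNCaP-Abl cells, with 3 arrays each for the control vector and wild-type SPOP and 2 for each mutant. Between 17485 and 19677 of the 47323 probes were detected per array. The median signal was 123 to 130 on control arrays, 120 to 126 on wild-type SPOP arrays and 109 to 123 on mutant arrays, and the first SPOP F133V array was the dimmest. Arrays of 1 group correlated at Pearson r of 0.990 to 0.995 over the 12227 tested genes, and arrays of different groups at 0.983 to 0.992. The 2 SPOP F133V arrays correlated at 0.9903. The second of them was closer to SPOP F102C array 2 (0.9924) and SPOP F133L array 1 (0.9919) than to the first. No array repeated another. The first principal component held 26.5% of the variance and ordered the arrays from control vector through wild-type SPOP to the mutants, while the second, with 17.7%, set wild-type SPOP apart from the other groups.

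The SPOP transcript itself was examined first. The SPOP probe ILMN_2397024 was detected on all 12 arrays, at a log2 level of 10.18 ± 0.04 (SD, n = 3) with control vector, 10.13 ± 0.11 (SD, n = 3) with wild-type SPOP and 10.05 ± 0.14 (SD, n = 6) with the mutants. The difference between wild-type SPOP and control vector was -0.05 ± 0.10 (SE; adjusted p = 0.841), and that between the mutants and wild-type SPOP -0.09 ± 0.08 (SE; adjusted p = 0.553). A second SPOP probe was detected on 1 array. Where these probes lie relative to the expressed constructs is not given in the sources used here, so the SPOP signal checks neither the labels nor the induction.

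**Figure D1:**
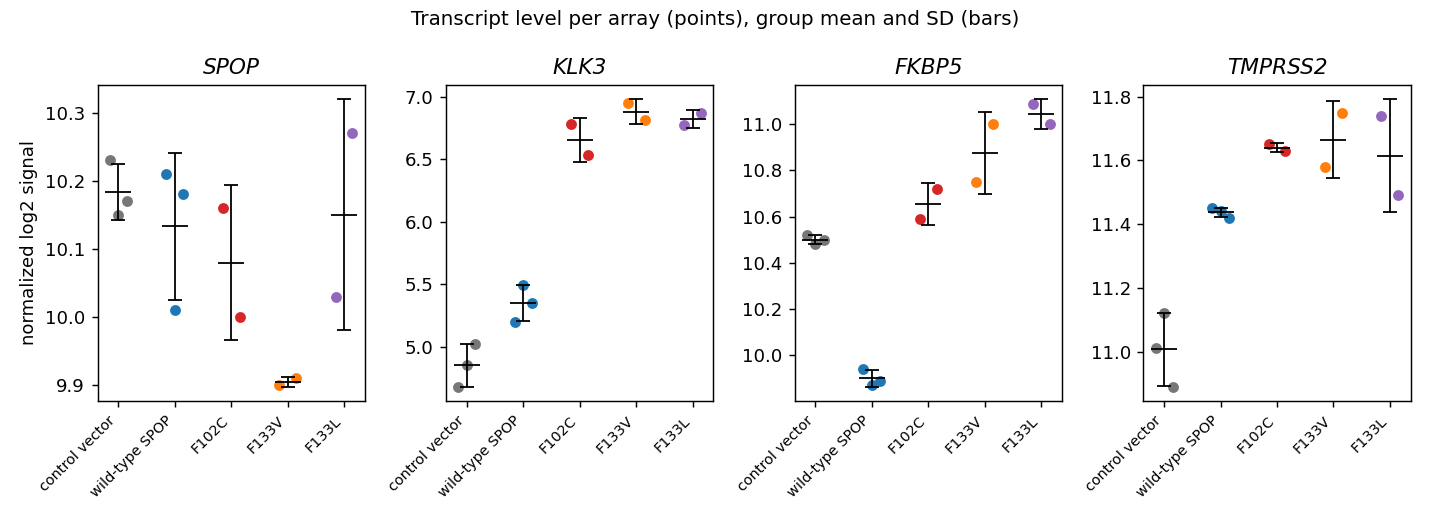
Normalized log2 signal of SPOP, KLK3, FKBP5 and TMPRSS2 on each of the 12 arrays by group, with each array as a point and the group mean and SD as a bar and whiskers; the vertical scale differs between panels. The 6 mutant arrays had KLK3 levels of 6.53 to 6.95, above all arrays of the other groups, while FKBP5 was lowest on the 3 wild-type SPOP arrays (9.87 to 9.94).

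The comparison of wild-type SPOP with control vector asked what the intact adaptor changes. Wild-type SPOP arrays had lower FKBP5, an androgen-induced co-chaperone of steroid receptors, by -0.60 ± 0.09 on the log2 scale (SE, n = 3 and 3; adjusted p = 0.00258). They had higher CDKN1A, the cyclin-dependent kinase inhibitor p21, by 1.26 ± 0.13 (adjusted p = 0.000115). In all, 752 genes changed, of which 377 rose and 375 fell, and 84 changed over 2-fold.

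The largest rises belonged to the testis-specific TSPY family, with a log2 change of 3.80 ± 0.10 for TSPY2, 3.43 ± 0.09 for TSPY8 and 2.49 ± 0.15 for TSPY4. TSPY8 was detected on 2 and TSPY4 on 1 of 3 control arrays, so their folds are limited by the detection floor. TSPY1 and TSPY3, chosen after their values were seen, differed by 0.30 (adjusted p = 0.596) and -0.39 (adjusted p = 0.357). The copies are similar in sequence, so which of them carries the signal is uncertain. SERPINI1, the serine protease inhibitor neuroserpin, rose by 2.36 ± 0.09, EEF1A2, a translation elongation factor, by 2.09 ± 0.15, GASK1B by 2.04 ± 0.15 and TSPAN7, a tetraspanin, by 2.00 ± 0.10. TLL1, a secreted metalloprotease, was at least 4.14-fold higher, CA1, a carbonic anhydrase, at least 3.84-fold and PLXDC2 at least 3.80-fold, each detected on 0 of 3 control arrays. The largest fall was that of the interferon-induced gene IFI44, at -4.15 ± 0.13, a 17.8-fold difference. TMEFF2, a transmembrane protein of the prostate, fell by 2.69 ± 0.11, the transcriptional regulator AFF3 by 2.54 ± 0.18, the adrenergic receptor ADRA2A by 2.25 ± 0.14 and the homeobox gene MKX by 1.97 ± 0.17. VCX3B, VCX and VCX3A, near-identical X-linked genes expressed in testis, changed by -2.83 ± 0.14, -2.69 ± 0.14 and -2.44 ± 0.14, and TRIM51 by -2.10 ± 0.13.

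Androgen-induced genes were lower with wild-type SPOP on balance. Of 27 measured, 8 fell, 2 rose and 17 did not pass, with a median of -0.10 (camera adjusted p = 0.00377), or -0.26 with arrays scaled to equal medians, -0.05 with the detected-probe covariate, and -0.06 and -0.04 without control array 2 or 3. Adjusted over the list alone, 12 fell and 2 rose. PMEPA1 fell by 1.70 ± 0.10, the prostaglandin receptor PTGER4 by 1.37 ± 0.12 and the elongation factor partner EAF2 by 0.61 ± 0.09. Against this direction, KLK3, which encodes prostate-specific antigen, rose by 0.49 ± 0.12 (adjusted p = 0.0314) from a control level detected on 1 of 3 arrays. The serine protease TMPRSS2 rose by 0.43 ± 0.10 (adjusted p = 0.0271). When each of the 12 arrays was left out in turn, the KLK3 call was lost in 4 fits (adjusted p up to 0.118) and the TMPRSS2 call in 5 (up to 0.0860). KLK2 differed by 0.17 ± 0.12 (adjusted p = 0.472). Of 13 androgen-repressed genes 3 rose and 0 fell, with a median of 0.21 (adjusted p = 0.000113; 4 rose adjusted over the list alone). They were SERPINI1, the kinase inhibitor CAMK2N1 at 1.99 ± 0.18 and the opioid receptor OPRK1 at 1.11 ± 0.20.

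Genes of DNA replication were lower. Of 24 measured on the G1/S and DNA replication list, 7 fell and 0 rose, with a median of -0.33 (adjusted p = 5.0e-09; 15 fell adjusted over the list alone). The replication licensing factor CDT1 fell by 0.82 ± 0.16, the helicase subunits MCM4 and MCM7 by 0.50 ± 0.09 and 0.49 ± 0.10, and UHRF1, which maintains DNA methylation, by 0.45 ± 0.09. Without 1 array the MCM7 call was lost in 4 of 12 fits (adjusted p up to 0.0623) and the UHRF1 call in 3 (up to 0.0610). The 24 genes of the G2/M and mitosis list did not move, with a median of -0.03 (adjusted p = 0.735) and 0 genes past the threshold. Of 18 p53 targets 5 rose and 0 fell, with a median of 0.17 (adjusted p = 0.00202; 6 rose adjusted over the list alone), which became adjusted p = 0.142 with an estimated correlation. Besides CDKN1A these included GDF15 at 0.80 ± 0.14, TP53INP1 at 0.74 ± 0.09 and TIGAR at 0.47 ± 0.10, whose call was lost in 3 fits without 1 array (adjusted p up to 0.0646).

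Of 17 ER chaperones and unfolded protein response genes 7 fell and 0 rose, with a median of -0.36 (adjusted p = 2.9e-06; 10 fell adjusted over the list alone). MANF fell by 0.55 ± 0.10, the co-chaperone DNAJC3 by 0.54 ± 0.12, CRELD2 by 0.52 ± 0.10 and the chaperone HSP90B1 by 0.52 ± 0.11. Leaving out each array in turn lost the DNAJC3 call in 4 of 12 fits (adjusted p up to 0.0691), HSP90B1 in 3 (up to 0.0666) and CRELD2 in 1 (0.0554). On the ATF4 list of 24 genes 4 fell and 1 rose, with a median of -0.26 (adjusted p = 0.000145; 12 fell and 2 rose adjusted over the list alone). The amino acid transporter SLC7A5 fell by 0.70 ± 0.09, STC2 by 0.45 ± 0.08 and the serine hydroxymethyltransferase SHMT2 by 0.39 ± 0.09 (lost in 4 fits without 1 array, adjusted p up to 0.0951), while DDIT4, an inhibitor of mTORC1 signalling, rose by 0.62 ± 0.10. Of 15 MYC and nucleolar targets 2 fell, NOP16 by 0.33 ± 0.08 and FBL by 0.34 ± 0.09, and 0 rose, with a median of -0.19 (adjusted p = 0.000579; 5 fell adjusted over the list alone). Without 1 array the FBL call was lost in 12 of 12 fits (adjusted p of 0.0504 to 0.151) and the NOP16 call in 5 (up to 0.110). The list of basal and other carcinoma line markers had 3 measured genes, of which VIM fell by 1.28 ± 0.11 (1 past the threshold; 2 adjusted over the list alone; camera adjusted p = 0.00963). Its call was lost with adjusted p = 0.174 with an estimated correlation, without control array 3 (adjusted p = 0.0775) and without the probe filter (adjusted p = 0.206).

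Of the 8 lists that moved in this comparison, 6 were also past the threshold with an estimated correlation. The count of 752 genes fell to 414 and 427 without control array 1 or 2, and to 433, 406 and 403 without wild-type SPOP array 1, 2 or 3. With arrays scaled to equal medians 169 of 593 changed genes rose.

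The comparison of the mutants with wild-type SPOP addressed what the mutations alter. SLC26A3, a chloride and bicarbonate exchanger, rose by 2.24 ± 0.09 (SE, n = 6 and 3; adjusted p = 1.6e-07), and the serum and glucocorticoid-regulated kinase SGK1 by 1.86 ± 0.08 (adjusted p = 4.8e-07). KLK3 rose by 1.44 ± 0.10 (adjusted p = 1.4e-05) and FKBP5 by 0.96 ± 0.08 (adjusted p = 3.2e-05), and each was higher on all 6 mutant arrays than on any of the 3 wild-type SPOP arrays. In all, 1437 genes changed, of which 681 rose and 756 fell, and 42 changed over 2-fold.

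Other large rises were those of the proteoglycan SPOCK1 (1.48 ± 0.09), the epithelial keratin KRT19 (1.46 ± 0.11), the pepsinogen PGC (1.45 ± 0.14), the growth factor receptor FGFR3 (1.37 ± 0.12), the cold-sensing channel TRPM8 (1.34 ± 0.11), OTULINL (1.31 ± 0.09) and TM4SF1 (1.28 ± 0.10). The largest falls were those of the interferon-induced genes IFIT2 (-1.63 ± 0.17) and IFIT1 (-1.19 ± 0.17), SDCBP2 (-1.57 ± 0.12), CAMK2N1 (-1.31 ± 0.16) and TMEM140 (-1.06 ± 0.12). The histone genes H2BC11 (-1.25 ± 0.13), H2BC4 (-1.24 ± 0.18), H2BC6 (-1.22 ± 0.16) and H3C7 (-1.06 ± 0.09) and TP53INP1 (-1.10 ± 0.08) were also among the 10 largest falls.

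Androgen-induced genes were higher in the mutants than other genes were. Of 27 measured, 13 rose and 0 fell, with a median of 0.32 (camera adjusted p = 1.2e-14; 17 rose adjusted over the list alone). With arrays scaled to equal medians, where the median over all genes was -0.26, the list's median was 0.03 and remained above other genes (adjusted p = 1.9e-13), so the size of its rise depends on the scaling. Besides KLK3, FKBP5 and TRPM8, NDRG1 rose by 1.19 ± 0.08 and EAF2 by 1.16 ± 0.08. KLK2 differed by 0.35 ± 0.11 (adjusted p = 0.0549) and TMPRSS2 by 0.21 ± 0.09 (adjusted p = 0.149). The TMPRSS2 difference turned to -0.08 with arrays scaled to equal medians. Of 13 androgen-repressed genes 8 fell and 1 rose, with a median of -0.43 (adjusted p = 4.7e-05; the same counts adjusted over the list alone). CAMK2N1 and SERPINI1 fell, the latter by 0.52 ± 0.08. The steroid-conjugating enzyme UGT2B15 fell by 0.61 ± 0.09, with a second probe of opposite sign, and its relative UGT2B28 rose by 0.62 ± 0.10.

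Replication genes were higher in the mutants than in wild-type SPOP. Of 24 genes 9 rose and 0 fell, with a median of 0.26 (adjusted p = 2.9e-07; 11 rose adjusted over the list alone), among them CDT1 (0.84 ± 0.14), UHRF1 (0.56 ± 0.08), the chromatin assembly factor CHAF1A (0.49 ± 0.10) and MCM5 (0.40 ± 0.09). The MCM5 call was lost in 2 of 12 fits without 1 array (adjusted p up to 0.0955) and the CHAF1A call in 1 (0.0547). With arrays scaled to equal medians, where the median over all genes was -0.26, the list's median was -0.02 and remained above other genes (adjusted p = 0.000323). The G2/M and mitosis list had a median of -0.03 (adjusted p = 0.503), with 2 genes lower and 0 higher. Of 18 p53 targets 10 fell and 0 rose, with a median of -0.45 (adjusted p = 6.3e-07; 12 fell adjusted over the list alone). CDKN1A fell by 1.02 ± 0.11, SPATA18 by 1.05 ± 0.12 and SESN1 by 0.73 ± 0.12. Neither the replication list nor the p53 targets passed in the mutants against control vector. The same wild-type SPOP arrays enter both main comparisons with opposite sign, so opposite medians in the 2 comparisons are partly built in.

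Of 11 NRF2 targets, which respond to oxidative stress, 5 fell and 0 rose, with a median of -0.28 (adjusted p = 0.000815; 6 fell adjusted over the list alone). The quinone reductase NQO1 fell by 0.97 ± 0.09, the cystine transporter SLC7A11 by 0.83 ± 0.12, the thioredoxin reductase TXNRD1 by 0.45 ± 0.09 and the malic enzyme ME1 by 0.36 ± 0.09 (lost in 4 of 12 fits without 1 array, adjusted p up to 0.127). Of 18 hypoxia and glycolysis genes 4 rose and 1 fell, with a median of 0.16 (adjusted p = 0.000995; 5 rose and 1 fell adjusted over the list alone). With arrays scaled to equal medians the medians of this list and of the metallothioneins turned to -0.08 and -0.08. NDRG1, the glycolytic regulator PFKFB3 (0.80 ± 0.10) and the glucose transporter SLC2A1 (0.71 ± 0.10) rose, and INSIG2 fell by 0.42 ± 0.08 (lost in 1 fit, adjusted p = 0.0524). Of 7 metallothionein list genes 3 rose and 0 fell (adjusted p = 0.0359; 4 rose adjusted over the list alone), MT1F by 0.45 ± 0.08, MT1X by 0.38 ± 0.09 and the zinc exporter SLC30A1 by 0.45 ± 0.11. Without 1 array the SLC30A1 call was lost in 4 fits (adjusted p up to 0.122) and MT1X in 2 (up to 0.113). The list call was lost in 5 of 13 processing alternatives (adjusted p up to 0.357). It was also lost with adjusted p = 0.208 with an estimated correlation, and with adjusted p up to 0.0717 without wild-type SPOP array 1 or 3, SPOP F102C array 1 or SPOP F133L array 2.

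The other lists did not pass in this comparison. Their medians were 0.03 for SPOP substrate transcripts, -0.02 for receptor coregulators and pioneer factors, -0.05 for cullin-RING ligase components, -0.02 for proteasome subunits, -0.13 for cholesterol synthesis and uptake, 0.03 for fatty acid synthesis and -0.22 for steroid hormone metabolism. They were 0.13 for ATF4 targets, 0.09 for ER chaperones, -0.08 for heat shock, -0.11 for interferon-stimulated genes, -0.12 for NF-kB targets, 0.12 for immediate early genes and 0.11 for MYC and nucleolar targets. Among marker lists they were 0.05 for luminal epithelium, 0.28 for neuroendocrine cells (3 measured), 0.15 for basal and other carcinoma lines (3 measured), 0.13 for fibroblasts (5 measured) and 0.08 for immune cells (4 measured).

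Of the 7 lists that moved, all but the metallothioneins passed with an estimated correlation. The count of 1437 genes fell to 601, 765 and 700 without wild-type SPOP array 1, 2 or 3, and to 308 with the number of detected probes per array as a covariate. With arrays scaled to equal medians, which lie among undetected probes, 141 of 4617 changed genes rose. With equal medians of the probes detected on all arrays 1644 of 2204 rose, and the median over all genes was 0.10.

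**Figure D2:**
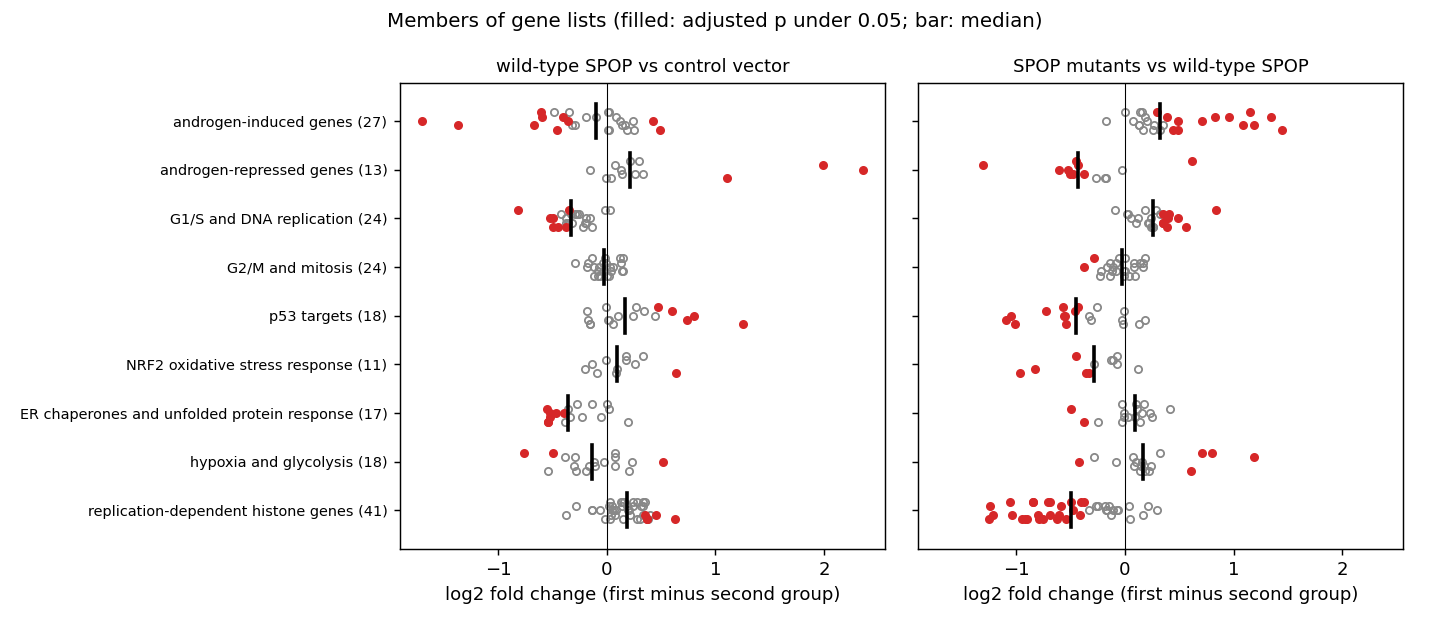
Log2 fold change of each measured member (points) of 8 gene lists and the histone genes in wild-type SPOP against control vector (left) and the mutants against wild-type SPOP (right); filled points are past an adjusted p of 0.05 and bars are medians. The androgen-induced list has a median of -0.10 on the left and 0.32 on the right, and the p53 targets 0.17 and -0.45. The same wild-type SPOP arrays enter both panels with opposite sign, so opposite medians are partly built in.

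Each mutant was also compared with wild-type SPOP alone, on 2 arrays against 3. SLC26A3 rose in SPOP F102C by 1.83 ± 0.11, in SPOP F133V by 2.30 ± 0.11 and in SPOP F133L by 2.60 ± 0.11. SGK1 rose by 1.35 ± 0.11, 1.98 ± 0.11 and 2.25 ± 0.11 in the same order, and KLK3 by 1.31 ± 0.13, 1.54 ± 0.13 and 1.48 ± 0.13. FKBP5 rose by 0.76 ± 0.10, 0.97 ± 0.10 and 1.15 ± 0.10, and IFIT2 fell by 1.57 ± 0.22, 1.55 ± 0.22 and 1.76 ± 0.22 (lost in 1 fit without 1 array for SPOP F102C, adjusted p = 0.0556). Among the 3 largest changes of a single mutant were also a rise of FGFR3 (1.40 ± 0.15) and a fall of CA1 (-1.41 ± 0.15) in SPOP F102C. In SPOP F133V they included SPOCK1 (1.72 ± 0.11) and SDCBP2 (-1.84 ± 0.16), and in SPOP F133L KRT19 (1.79 ± 0.14) and SDCBP2 (-1.76 ± 0.16). KLK2 differed by 0.46 ± 0.14 (adjusted p = 0.0909) in SPOP F102C, by 0.52 ± 0.14 (adjusted p = 0.0434) in SPOP F133L, a call lost in 8 of 12 fits without 1 array (adjusted p up to 0.193), and by 0.05 ± 0.14 (adjusted p = 0.851) in SPOP F133V, where it turned to -0.46 with equal array medians. TMPRSS2 passed in none of them, with 0.20 ± 0.11, 0.23 ± 0.11 and 0.18 ± 0.11.

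The androgen-induced list was higher in every mutant, with 10, 11 and 13 of 27 genes up, 0 down, and medians of 0.28, 0.38 and 0.39 in SPOP F102C, SPOP F133V and SPOP F133L (12, 15 and 15 up adjusted over the list alone; adjusted p = 5.6e-14, 1.2e-11 and 4.6e-14). The p53 targets fell in each, with 7 of 18 genes down in every mutant and medians of -0.40, -0.44 and -0.41 (9, 10 and 10 down adjusted over the list alone, with 1 up in SPOP F133V). For SPOP F133V this call gave adjusted p = 0.0876 with an estimated correlation. SPOP F102C changed 385 genes (206 rose, 179 fell), SPOP F133V 997 (442 rose, 555 fell) and SPOP F133L 801 (395 rose, 406 fell).

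The log2 changes of the mutants correlated across genes at Pearson r of 0.66 to 0.69 for the 3 pairs, where unchanged groups set against the same wild-type SPOP arrays gave 0.40. Genes are not independent replicates. The covariances were 0.049, 0.049 and 0.057 against a simulated 0.0098 for each pair. For SPOP F133V and SPOP F133L, 227 genes rose and 223 fell in both, against 14.3 and 18.4 for independent lists. The 3 wild-type SPOP arrays were not split between the comparisons, so part of this excess may come from the shared arrays. Without SPOP F133V array 1 its count was 245, without SPOP F102C array 1 or 2 that mutant's counts were 74 and 94, and without SPOP F133L array 1 or 2 they were 372 and 279. Leaving out wild-type SPOP array 1, 2 or 3 gave 173, 240 and 213 for SPOP F102C, 483, 608 and 553 for SPOP F133V, and 369, 453 and 419 for SPOP F133L. With equal array medians 67 of 412, 75 of 6796 and 103 of 1422 changed genes rose in SPOP F102C, SPOP F133V and SPOP F133L. With the detected-probe covariate the counts were 294, 5 and 384, and in fits of only the arrays compared 252, 343 and 435. The medians over all genes with equal array medians were -0.13, -0.48 and -0.20. With the detected-probe scaling 1870 of 2297 rose in SPOP F133V and 679 of 986 in SPOP F133L.

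Against the control vector, the largest changes of the mutants went the same way as those of wild-type SPOP. TSPY2 rose by 4.00 ± 0.08, TSPY8 by 3.65 ± 0.08 and TSPY4 by 2.63 ± 0.13 (SE, n = 6 and 3), and IFI44 fell by 4.58 ± 0.11, TMEFF2 by 3.15 ± 0.09 and ADRA2A by 2.38 ± 0.12. IFI44 was detected on 3 of 6 mutant arrays and its mean there lay at the detection floor, so its fall is limited by that floor. KLK3 rose by 1.94 ± 0.10, TMPRSS2 by 0.63 ± 0.09 and KLK2 by 0.52 ± 0.11. Without 1 array the KLK2 call was lost in 1 of 12 fits (adjusted p = 0.0504) and the FKBP5 call in 1 (0.0529). FKBP5 rose by 0.36 ± 0.08 (adjusted p = 0.0127), a change that turned to -0.11 with equal array medians, where the median over all genes was -0.37. With equal medians of the detected probes the FKBP5 change was 0.37. In all, 1494 genes changed, of which 684 rose and 810 fell.

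Androgen-induced genes were higher than in the control, with 12 of 27 up, 2 down and a median of 0.28 (adjusted p = 6.0e-05; 15 up and 4 down adjusted over the list alone), and the median turned to -0.13 with equal array medians while it remained above other genes (adjusted p = 0.00987). NDRG1 rose by 0.89 ± 0.08 and TRPM8 by 1.15 ± 0.11, while PMEPA1 fell by 0.99 ± 0.09. ER chaperones were lower, with 8 of 17 down, 0 up and a median of -0.29 (adjusted p = 0.000344; 10 down adjusted over the list alone). They included HSPA5, the chaperone BiP (-0.76 ± 0.09), HYOU1 (-0.56 ± 0.11), HSP90B1 (-0.53 ± 0.09) and MANF (-0.44 ± 0.08). Of 23 interferon-stimulated genes 9 fell and 1 rose, with a median of -0.21 (adjusted p = 0.00741; 10 fell and 1 rose adjusted over the list alone). This call gave adjusted p = 0.176 with an estimated correlation. IFIT2 fell by 1.56 ± 0.17 and IFIT1 by 1.11 ± 0.17, and OASL was at least 1.58-fold lower, detected on 0 of 6 mutant arrays.

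Of 11 luminal epithelial markers 4 rose and 0 fell (median 0.09; adjusted p = 0.0491; 4 rose adjusted over the list alone), a median that turned to -0.25 with equal array medians, with adjusted p = 0.176 with an estimated correlation. They were the transcription factors SPDEF (0.76 ± 0.12) and HOXB13 (0.53 ± 0.12) and the keratins KRT8 (0.60 ± 0.10) and KRT18 (0.69 ± 0.13). On the ATF4 list 4 of 24 genes fell and 1 rose (median -0.11; adjusted p = 0.0491; 6 fell and 1 rose adjusted over the list alone), with adjusted p = 0.264 with an estimated correlation. SLC7A11 (-1.03 ± 0.12), SLC7A5 (-0.38 ± 0.08) and ASNS (-0.33 ± 0.08) fell, and NUPR1 rose by 0.88 ± 0.16. The ASNS call was lost in 3 of 12 fits without 1 array (adjusted p up to 0.0979) and HOXB13 in 1 (0.0735). The luminal call was lost in 5 of 13 processing alternatives (adjusted p up to 0.170) and the ATF4 call in 3 (up to 0.117). Both were also lost when single arrays were left out (adjusted p up to 0.0887 and 0.131), for both lists without control array 2, SPOP F102C array 2 or SPOP F133V array 1. The luminal call was lost too without SPOP F133L array 2, and the ATF4 call without control array 1, wild-type SPOP array 1 or 3, or SPOP F133L array 1.

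Of the 752 genes changed in wild-type SPOP against control vector, 374 changed the same way in the mutants against control vector, 184 up and 190 down. Independent lists would share 21.1 and 24.8. The changes of the 2 comparisons covaried by 0.0441 across genes against a simulated 0.00981, with r of 0.59 and a simulated 0.58. The 3 control arrays were not split between the 2 comparisons, so part of this excess may come from the shared arrays. The 18 genes changed over 4-fold in wild-type SPOP all changed the same way in the mutants, but 8 of them differed between the mutants and wild-type SPOP. In the mutants CA1, VCX, VCX3A, VCX3B, GASK1B and SERPINI1 lay closer to the control, and TMEFF2 and IFI44 further from it, with the same wild-type SPOP arrays in both comparisons. In the opposite direction, 22 genes passed in both comparisons with opposite signs. With equal array medians the median over all genes was -0.37 in the mutants against control vector. Of the rises over control vector in the mutants, only those of SLC26A3 (1.03) and OTULINL (0.33) then passed the threshold, while all the falls did. With equal medians of the detected probes the median over all genes was 0.106. All the rises then passed, while the falls of TICAM2 (-0.02) and ZNF134 (-0.09) did not, so which side passes depends on the scaling.

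Of 27 lists 5 moved in the mutants against control vector. The other lists did not pass, among them androgen-repressed genes, G1/S and DNA replication, and p53 targets. The count of 1494 genes fell to 943, 886 and 870 without control array 1, 2 or 3, and to 107 with the detected-probe covariate. With equal array medians 156 of 6935 changed genes rose, and with equal medians of the detected probes 2297 of 3031.

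Among the 3 mutants the F test called 3 genes, against 1443 at an unadjusted p under 0.05. In simulated data this test recovered 14.9% of genes changed by 0.5 log2 units, so small differences would mostly be missed. RGS2, a regulator of G-protein signalling, was higher in SPOP F133V than in SPOP F102C by 0.92 ± 0.10 (n = 2 and 2; adjusted p = 0.0157). THAP8 was at least 1.61-fold higher in SPOP F133V than in SPOP F102C and at least 1.58-fold higher than in SPOP F133L, detected on 0 of 2 arrays in each of the latter. Without 1 array the THAP8 call between SPOP F133L and SPOP F133V was lost in 9 of 12 fits (adjusted p up to 0.162), and the THAP8 and RGS2 calls between SPOP F133V and SPOP F102C in 3 each (up to 0.138). DSE, an epimerase of dermatan sulfate synthesis, was at least 1.97-fold higher in SPOP F102C than in SPOP F133V, a call lost in 2 of 12 fits (up to 0.138). The pairwise comparisons called 8 genes between SPOP F133V and SPOP F102C, 1 between SPOP F133L and SPOP F133V and 0 between SPOP F133L and SPOP F102C (1122 at an unadjusted p under 0.05 in limma). The F test count was 0 without any of control arrays 1, 2 and 3, wild-type SPOP array 3, SPOP F102C array 1 or 2, or SPOP F133V array 1. It was 1 without wild-type SPOP array 1, 8 and 5 without SPOP F133L array 1 or 2, and 36 without SPOP F133V array 2.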

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

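The fit with the number of detected probes as a covariate was chosen after the brightness of the arrays was seen, and the list tests between single mutants were not among the comparisons fixed beforehand.

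Of the 22 genes that changed in opposite directions against control vector in wild-type SPOP and in the mutants, 7 were named in the 2 main comparisons of the report. On the log2 scale the difference between mutants and wild-type SPOP was 2.24 for SLC26A3, 1.48 for SPOCK1, 1.31 for OTULINL, 1.16 for EAF2, 0.96 for FKBP5, -1.10 for TP53INP1 and -0.97 for NQO1. These genes were picked for changes in opposite directions, so a large difference follows from the choice. The rise over control vector in the mutants was no longer past the threshold with equal array medians for FKBP5 (-0.11), EAF2 (0.07) and SPOCK1 (0.30), and was for SLC26A3 (1.03) and OTULINL (0.33). With equal medians of the detected probes all these rises passed, at 0.37 for FKBP5, 0.55 for EAF2 and 0.78 for SPOCK1. The falls of TP53INP1 and NQO1 passed with either scaling.

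The androgen-induced genes were higher in the mutants than in wild-type SPOP, a pattern to which FKBP5 and EAF2 belong. Of the 6 mutant arrays 5 had fewer detected probes than every wild-type SPOP array. With the number of detected probes as a covariate the list's median was 0.39 against 0.32 without it (camera adjusted p = 1.3e-13). The covariate overlaps with the groups, so this does not exclude brightness as a cause. A few members do not carry the list alone, since without KLK3, TRPM8 and NDRG1 its median was 0.28 (adjusted p = 1.4e-10). A candidate explanation is a difference between mutant and wild-type SPOP in androgen-dependent transcription, which stays a hypothesis drawn from these arrays and was not tested. Differences between the transfected lines other than the construct stay open, because each construct is represented by 1 group of cultures.

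The 3 mutants differed in DSE (F test adjusted p = 0.0431), THAP8 (0.0208) and RGS2 (0.0208). Between SPOP F133L and SPOP F102C the lists of androgen-induced genes (adjusted p = 0.0165, higher in SPOP F133L), hypoxia and glycolysis (1.5e-05, higher) and G2/M and mitosis (0.00446, lower) differed. Between SPOP F133L and SPOP F133V the hypoxia and glycolysis list was higher (0.000304), and the G2/M and mitosis list (0.0397) and MYC and nucleolar targets (0.0199) were lower. MYC and nucleolar targets were higher in SPOP F133V than in SPOP F102C (0.0409). With an estimated correlation only the hypoxia and glycolysis difference between SPOP F133L and SPOP F102C passed among these 7 (adjusted p = 0.0266).

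Probes with no gene listed were left out of the comparisons. Of 6614 such probes that passed the filter, 111 were past the threshold in wild-type SPOP against control vector and 291 in the mutants against wild-type SPOP, when every probe was its own feature. These are 1.68% and 4.40% of them, against 3.84% and 8.05% of the named probes.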

How the results depend on the processing

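The androgen-induced list kept its direction and its side of the threshold in both main comparisons under every alternative. Its medians were 0.29 to 0.37 (mutants against wild-type SPOP) and -0.15 to -0.04 (wild-type SPOP against control vector) when 1 array was left out, and 0.028 and -0.257 with equal array medians, the alternative that moved both most. Of 166 named gene results 92 kept their call and direction in every alternative, and 1887 of 1992 did so when single arrays were left out. Except where a sentence below gives it by construction, the cause was not tested for any shift. The covariate and the detected-probe scaling were added after the data were seen.

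Counts of changed genes without 1 array were 403 to 764 (wild-type SPOP against control vector), 601 to 1437 (mutants against wild-type SPOP), 870 to 1520 (mutants against control vector), 74 to 381 (SPOP F102C), 245 to 1064 (SPOP F133V), 279 to 799 (SPOP F133L) and 0 to 36 (among the mutants). Lists moved numbered 7 to 9, 6 to 9 and 3 to 6 in the first 3. The SPOP difference between wild-type SPOP and control vector ran from -0.088 to 0.015, turning sign without wild-type SPOP array 2. Small differences that turned sign were CAV1 in that comparison (-0.133 to 0.121), KLK2 in SPOP F133V (-0.032 to 0.137), and SPOP in SPOP F102C (-0.136 to 0.022) and in SPOP F133L (-0.098 to 0.136). Where an array left a mutant with 1 array, that array was assumed to vary like the other groups.

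In the order wild-type SPOP against control vector, mutants against wild-type SPOP, mutants against control vector, SPOP F102C, SPOP F133V, SPOP F133L and among the mutants, the main counts were 752, 1437, 1494, 385, 997, 801 and 3. Counts that moved by over 1.5 times follow. Equal array medians lie among undetected probes. With them the counts were 4617 (mutants against wild-type SPOP), 6935 (mutants against control vector), 6796 (SPOP F133V), 1422 (SPOP F133L) and 326 (among the mutants). FKBP5 in the mutants against control vector then turned to -0.11, TMPRSS2 and MT1H in the mutants against wild-type SPOP to -0.078 and -0.084, KLK2 and TMPRSS2 in SPOP F133V to -0.46 and -0.29, and SPOP in SPOP F133L to -0.21. With equal medians of the detected probes the counts were 2204, 3031 and 2297 (mutants against wild-type SPOP, mutants against control vector, SPOP F133V) and 0 among the mutants, with 8 lists moved against control vector and CAV1 in wild-type SPOP against control vector at 0.037. With the detected-probe covariate they were 343 (wild-type SPOP against control vector), 308 (mutants against wild-type SPOP), 107 (mutants against control vector), 5 (SPOP F133V), 384 (SPOP F133L) and 0 among the mutants, with 3 lists and SPOP in SPOP F133L at -0.026. The covariate overlaps with the SPOP F133V group, whose arrays have the fewest detected probes, so it removes group differences too.

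With the authors' processed values the counts were 1286 (wild-type SPOP against control vector), 895 (SPOP F102C), 1314 (SPOP F133L) and 17 (among the mutants). Without background correction they were 1375 (wild-type SPOP against control vector), 996, 1559 and 1459 (SPOP F102C, SPOP F133V, SPOP F133L) and 42 (among the mutants), and the trended and robust spread gave 1259, 895, 1516, 1372 and 57 in the same order. Normexp gave 721 (SPOP F102C), 1227 (SPOP F133L) and 23 (among the mutants). Array weights gave 672 for SPOP F102C, the stricter detection filter 583 for SPOP F102C and 15 among the mutants, and every probe as a feature 0 among the mutants and 9 lists against control vector. Fits of only the arrays compared, which have fewer degrees of freedom, gave 252, 343 and 435 for SPOP F102C, SPOP F133V and SPOP F133L and 0 among the mutants. For lists, the estimated correlation left 2 of 5 in the mutants against control vector, and fry called 17, 15 and 21 lists in the 3 comparisons, since it does not set a list against other genes. Leaving out the filter moved no count by over 1.5 times.

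Same replicate numbers did not pair the arrays: the correlations of their deviations ran from -0.06 to 0.04 over 21 pairs, with 0 over 0.1. With the replicate block the counts were 672 (mutants against wild-type SPOP), 920 (mutants against control vector), 178, 512 and 408 for SPOP F102C, SPOP F133V and SPOP F133L, and 0 among the mutants, and KLK2 in SPOP F133V turned to -0.015. The block for bead chips was not run. Signal over background limits the genes near the detection floor, such as KLK3 in the control arrays, whose folds are compressed.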

Other observations

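The tests of the histone genes, of the multicopy families, of a separate control line and of cycling cells were chosen after the results were seen. The others were chosen before, except the detected-probe covariate, which was added after the data were seen.

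Replication-dependent histone genes, which were not among the fixed lists, were lower on balance in the mutants. Of 41 measured, 25 fell, 0 rose and 16 did not pass in the mutants against wild-type SPOP, with a median of -0.50 and single genes between -1.25 and 0.29. H2BC21 fell by 1.04 ± 0.08, H2AC6 by 0.92 ± 0.08 and H1-2 by 0.84 ± 0.09, chosen after their values were seen. In wild-type SPOP against control vector 5 rose and 0 fell, with a median of 0.19 (camera p = 0.00436 with an estimated correlation), and in the mutants against control vector 18 fell and 0 rose, with a median of -0.33. Relative to all genes the list stayed below 0 in the mutants against wild-type SPOP in all 13 alternatives, with medians of -0.67 to -0.11. Many of these genes are near copies, so the probes can share signal.

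Relative to other genes, histone genes and p53 targets were lower, and G1/S genes higher, in the mutants than in wild-type SPOP, although the G1/S median turned to -0.02 with equal array medians. In the mutants against control vector the p53 and G1/S lists did not pass, while histone genes were lower. With the detected-probe covariate the p53 targets had a median of -0.46 (camera adjusted p = 4.7e-07), against -0.45 without it. The covariate overlaps with the groups, so this does not exclude array brightness as a cause. The histone genes were picked because 4 of them were among the 10 largest falls. The other 37 had a median of -0.415 (camera p = 4.9e-05 with an estimated correlation). They are near copies of those 4 in part and were measured on the same arrays, so this is not a separate test of the choice. Fewer cycling cells in the wild-type SPOP cultures would raise G2/M genes in the mutants, by at least 0.13 under the criterion set. Their median was -0.032, against 0.26 for G1/S genes. A bootstrap over the 24 genes gave a 95% interval of -0.12 to 0.04, which holds no spread between arrays. The list also differed between SPOP F133L and both other mutants, so the pooled median does not exclude this explanation. A shift within the cell cycle or in p53 activity may underlie the pattern, and neither was tested.

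The largest changes between control vector and wild-type SPOP went the same way in the mutants, with 6 of the 18 genes changed over 4-fold closer to the control there and 2 further from it. The changes covaried by 0.0441 across genes, above the highest simulated value of 0.0104 in 100 draws, with r of 0.59 and a simulated 0.58. Independent noise of the shared control arrays alone did not reach this covariance. Deviations of an array common to many genes were not simulated. Of the 18 genes changed over 4-fold, 11 lay outside the TSPY, VCX and TRIM49/TRIM51 families, so cross-hybridisation within these families cannot account for those 11. It stays open for the 7 within them. A control line that had drifted from the SPOP lines before induction cannot be told apart from an effect shared by all forms of SPOP, because the design has 1 control group and all 18 of the 18 genes changed the same way in the mutants.

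Other splits of the same arrays were fitted as 2 groups. For the mutants against wild-type SPOP, 1 of 84 splits, the real one, gave as many changed genes (1007, with 0 at most in the others). It also gave the smallest camera p for the androgen-induced list (9.4e-15, with 1.8e-08 the smallest other). A share of 1 in 84 is the smallest these splits can give, and the other splits mix arrays of different constructs. That mixing can add spread within the sides, so the splits do not exclude chance for either. For the number of lists moved, 12 of 84 splits gave at least the real 7, with 9 at most in the others, so chance cannot be excluded for that count. For the mutants against control vector 1 of 84 splits, the real one, gave as many genes (955, with 1 at most in the others). The same limit holds for this gene count. For lists, 3 of 84 splits gave at least the real 5, with 8 at most in the others. That share is under 0.05, but a split that mixes the groups moved more lists than the real one. Chance can therefore not be excluded for the list count. Wild-type SPOP against control vector allows 10 splits, too few for a share under 0.05. The real split gave 728 genes (0 at most in the others), 8 lists (3 at most in the others) and a list p of 0.00256 (0.0325 the smallest other), and 1 of 10 splits reached each of these.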
